A study of Mus musculus with 6 samples.

How the data were processed

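The labels list 6 MeDIP-seq samples of mouse embryonic stem cells, with 2 MeDIP samples and 1 input sample of parental V6.5 cells and the same of cells with a Tet2 hairpin. The deposited table had 1 MeDIP column per line and 1 input column whose name joins both lines. The column names give no replicate number, so whether the replicates were merged into each column is not stated in the sources used here. They were treated as 1 set of reads per line, and the line was taken from the column name, which no value in the table settled.

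The counts deposited by the authors were raw reads per window of 300 bp, per the file headers. The RPKM values in the table were computed by the authors from these counts, the window length and the read total of each column, per the file headers. Dividing counts by RPKM gave the same read total in every row of a column, and these totals were used as library sizes. The log2 fold changes in the authors' deposited table were parental over Tet2kd after a scaling between the columns. Here the direction is Tet2kd over parental, and ratios of CPM (reads over the read total of their column) use the read totals alone. The p-value of each window was deposited by the authors, with an adjusted p that was the p times a constant, 7963118, taken here as the number of windows tested (Bonferroni). Per the submitters' processing notes, the build was mm9 and the tools included bedtools and edgeR, without versions. The aligner, the handling of duplicate reads and the kind of scaling are not given in the sources used here. Reads in multi-copy sequence and stacks of duplicate fragments can raise single windows.

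The table listed only windows with a p under 0.0001, so windows without a difference were not analysed here and no rate over the genome was computed. No test between replicates could be run, and the design that had been fixed before the data were examined (a quasi-likelihood test over 4 libraries, CpG density classes, input of each line, gene lists) was replaced by a description of the authors' calls. Windows past an adjusted p of 0.05 in the authors' deposited table were merged within 300 bp by direction. The rule for the regions named in the text was fixed before the data were examined. Among merged regions with a mean of at least 20 reads over both MeDIP columns, it took the 12 highest and 12 lowest by log2 ratio of CPM, and in addition the 5 widest of each direction, with ties in width taken in genome order. A count of 0.5 was added for this ranking only. The requirement of the rule that every replicate lie on one side could not be applied. Gene names were not assigned to windows because the gene table at hand was of another build (GRCm38.p6), so neither the genes of the fixed lists nor Tet2 itself were placed.

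Ratios of reads in a region carry 95% exact intervals from the binomial distribution of the Tet2kd reads among both columns (Clopper-Pearson). A count of 0 was replaced by a floor of 3 reads in the column. Shares carry Wilson 95% intervals. These cover counting error only, since reads are not independent molecules and neighbouring windows share fragments. Segments with an excess of Tet2kd-higher windows were found as the run with the highest sum per chromosome, scoring each higher window as 1 and each lower window as -1. The interval of the segment's input ratio came from 2000 bootstrap draws of windows.

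The authors' test was rebuilt with edgeR 4.0.16 (R 4.3.3) as an exact test of the 2 columns. With a scaling offset of 0.20 on the log2 scale and an assumed coefficient of variation of 0.01, 100% of the p-values equalled the deposited ones within 0.01 on the log10 scale. Other assumed values were 0.05, 0.1, 0.2 and 0.4. On simulated data with the means of the listed windows, 20000 windows were tested at an assumed value of 0.01, 200 of them changed 4-fold. With a true value of 0.01, 98.5% of the changed windows and 0 of 19800 unchanged ones had a p under 0.0001. With a true value of 0.2, 95.5% of the changed and 6.91% of the unchanged windows did. Alternatives to the adjusted threshold, count minimum, scaling, merging distance, chromosomes and input minimum were also computed. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.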

Results

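DNA methylation was mapped in mouse embryonic stem cells by MeDIP-seq, in which an antibody against 5-methylcytosine pulls down methylated DNA fragments that are then sequenced. The parental cells were the V6.5 embryonic stem cell line, and the knockdown cells (Tet2kd) carried a short hairpin RNA against Tet2. Tet2 is an enzyme of the TET family, which oxidises 5-methylcytosine and so takes part in its removal. The labels list 6 samples, with 2 MeDIP samples and 1 input sample (DNA before the pull-down) of each line. The deposited table held 1 column of parental MeDIP reads, 1 column of Tet2kd MeDIP reads and 1 column of input reads of both lines together. The read totals behind these columns were 61067518 for parental MeDIP, 71630044 for Tet2kd MeDIP and 53129676 for the pooled input. With 1 column per line, none of the differences has a replicate check, and the p-values in the table compare these sets of reads, not the conditions. Which line a column belongs to was taken from its name, and no value in the table settled it, so every direction given here rests on those names. Were the names exchanged, 82.5% of the listed windows would be higher in Tet2kd cells in place of 17.5%. Intervals given here cover counting error only.

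The comparison asked where the methylation signal changed when Tet2 was knocked down. Most of the windows that differed had less MeDIP signal in the column named for Tet2kd cells. The table listed 177396 windows of 300 bp, of which 146356 were lower in Tet2kd cells and 31040 were higher, so that 17.5% were higher (Wilson 95% interval 17.3% to 17.7%, for counting alone). With read totals in place of the authors' scaling, 83236 lower and 31040 higher windows kept a p under 0.0001, and the share that was higher was 27.2%. The list was cut under the authors' scaling, so higher windows that would newly pass are missing and 27.2% is a minimum. At an adjusted p under 0.05 in the authors' deposited table, 40167 windows were lower and 2063 were higher. Merged where they lay within 300 bp of each other, these made 26779 regions that were lower and 1674 that were higher. The listed windows were 2.23% of the 7963118 windows that the authors tested, and the largest p in the list was 9.99e-05.

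The windows of each direction differed in their level. In the lower windows, the median read count was 114 in parental and 70 in Tet2kd cells, beside 13 in the pooled input. Relative to the pooled input, with each column scaled to its read total (CPM), parental signal there had a median of 7.83 and Tet2kd signal a median of 4.12. Signal of at least 2 times the input remained in Tet2kd cells in 80.7% of the lower windows that had an input read. In the higher windows, the median read count was 13 in parental and 64 in Tet2kd cells, beside 12 in the pooled input. Parental signal there was near the input, with a median ratio of 0.994, and Tet2kd signal had a median ratio of 4.14. The median log2 ratio of Tet2kd to parental CPM was -0.96 in the lower windows and 2.00 in the higher windows. A change of at least 4-fold was seen in 52.6% of the higher and in 2.05% of the lower windows. The list held only windows under a p limit, and windows with few reads need a larger ratio to reach it, so these levels and ratios were set in part by the selection and do not compare the sizes of gains and losses. All ratios here use read totals alone. The log2 fold changes in the authors' deposited table were set by a scaling that moved Tet2kd down by a further 0.20.

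**Figure D1:**
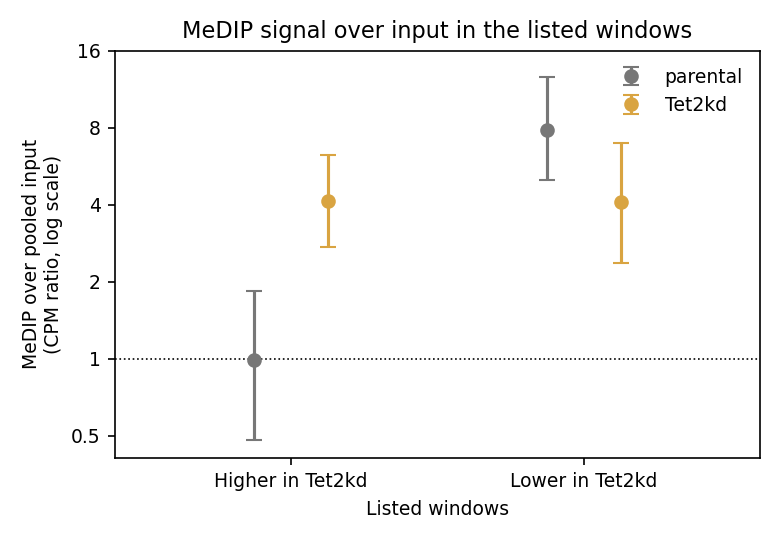
MeDIP reads over pooled input reads, both as CPM, on a log axis for parental (grey) and Tet2kd (ochre) cells, in the listed windows higher and lower in Tet2kd. Points are medians over windows and bars span the quartiles of the windows, not replicate error. In the higher windows parental cells sit at 0.994 and Tet2kd cells at 4.14, and in the lower windows at 7.83 and 4.12.

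Both counts depended on the scaling and on the spread that the test assumed. With read totals in place of the authors' scaling, 16968 of the listed windows passed as lower and 5376 as higher, so that 24.1% of them were higher against 4.89% with the authors' scaling. Windows outside the list could not be counted, so 24.1% is a minimum too. The deposited p-values were those of an exact test with an assumed coefficient of variation of 0.01 between cultures, and with 0.1 in its place 1453 windows passed as lower and 323 as higher. With 0.2, 11 windows passed as lower and 7 as higher, and with 0.4 none did.

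The regions with the highest ratio of Tet2kd to parental signal were small and had almost no parental reads. Ranking by ratio favours regions with few parental reads, so this was set in part by the rule. The 12 with the highest ratio were 1 or 2 windows wide and held 0 to 2 parental reads against 42 to 91 Tet2kd reads. The top region lay on chromosome 7 from 13718101 to 13718400 (mm9), with 0 parental and 56 Tet2kd reads, at least 15.9-fold higher in Tet2kd cells against a floor of 3 parental reads. The floor leaves out the counting error of the Tet2kd reads, and the exact 95% lower limit was 12.5. On chromosome 14, from 77095501 to 77095800, 0 parental and 49 Tet2kd reads were counted, which was at least 13.9-fold higher by the floor, with an exact lower limit of 10.9. A region on chromosome 9 from 95853901 to 95854200 had 0 parental and 42 Tet2kd reads, at least 11.9-fold higher by the floor, with an exact lower limit of 9.29. The regions on chromosome 6 from 15486601 to 15487200 and on chromosome 19 from 54020701 to 54021300 each had 1 parental read, against 84 and 80 Tet2kd reads. Their ratios were 71.6 (95% interval 12.5 to 2862) and 68.2 (11.9 to 2727). Parental signal there was 0.0512 and 0.0335 times the pooled input, and Tet2kd signal 3.66 and 2.28 times. The region on chromosome 17 from 85800001 to 85800600 had 2 parental and 91 Tet2kd reads, a ratio of 38.8 (10.4 to 325). The other 6 lay on chromosomes 2, 3, 6, 9, 10 and 12 and had ratios of 35.0 to 47.7. Input reads were present in each of the 12, from 2 to 29. Over the 12, parental signal was 0 to 0.435 times the pooled input and Tet2kd signal 2.10 to 17.8 times. The high ratios thus came with parental signal below the input, and do not measure the enrichment in Tet2kd cells.

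The 5 widest gained regions spanned 1200 to 1800 bp and had more moderate ratios. The widest lay on chromosome 6 from 115870801 to 115872600, where parental signal was 0.906 times the pooled input and Tet2kd signal 6.16 times. Its counts were 76 and 606 reads, a ratio of 6.80 (5.35 to 8.75). The region on chromosome 11 from 71658301 to 71659500 was above the input in both lines, with 526 parental and 1670 Tet2kd reads and a ratio of 2.71 (2.45 to 2.99). Likewise, a region on chromosome 1 from 13308001 to 13309200 went from 5.81 times the input in parental to 19.3 times in Tet2kd cells, a ratio of 3.33 (2.96 to 3.75). The remaining regions, on chromosome 4 from 139783201 to 139784400 and on chromosome 10 from 39690901 to 39692100, had ratios of 3.49 (2.84 to 4.33) and 2.50 (2.24 to 2.80).

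The region with the largest ratio of parental to Tet2kd signal was on chromosome X. From 103381801 to 103382700, 211 parental reads and 1 Tet2kd read were counted beside 29 input reads, so that parental cells were 247 times higher (95% interval 43.9 to 9821). In this region Tet2kd signal was 0.0256 times the pooled input, far below the background, while parental signal was 6.33 times. The input held 9.67 reads per window in this region, against 5.67 per listed window on chromosome X. The input of each line alone was not analysed here, so it is not known whether both lines carried this sequence in equal copies, and the ratio is one of reads, not of methylation per copy. Per the labels, the knockdown cells were made by electroporation with a hairpin plasmid and drug selection, and reads of plasmid sequence that is shared with the genome would be placed at the genomic position. Whether this region shares sequence with the plasmid was not checked here. If it does, added reads would belong to the cells with the plasmid, while these reads were in the column named for parental cells. Only in that case would this region bear on the names of the columns. Without that check the 247-fold value stays in doubt. The next region, on chromosome 5 from 145306201 to 145307700, spanned 5 windows with 443 parental and 33 Tet2kd reads, 15.7 times higher in parental cells (11.05 to 23.2). There, Tet2kd signal was 0.437 times the input and parental signal 6.88 times. On chromosome 13 from 116982901 to 116983500, 96 parental and 9 Tet2kd reads gave a ratio of 12.5 (6.32 to 28.2). On chromosome 15 from 29913601 to 29913900, 41 parental and 4 Tet2kd reads gave a ratio of 12.02 (4.35 to 46.2), with 0 input reads. The regions on chromosome 4 from 41288101 to 41288700 and on chromosome 8 from 38175301 to 38175900 were 9.53 (5.65 to 17.2) and 9.38 (5.94 to 15.6) times higher in parental cells. The other 6 of the 12, on chromosomes 2, 3, 4, 8, 9 and 12, had ratios of 8.53 to 9.85. Of these, the region on chromosome 4 from 142104901 to 142105200 no longer passed with read totals in place of the authors' scaling.

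The widest lower regions were broad, from 3900 to 6000 bp. The widest lay on chromosome 17 from 39979801 to 39985800 and held 10673 parental, 4168 Tet2kd and 9599 input reads. Parental signal there was 0.967 times the pooled input and Tet2kd signal 0.322 times, with parental cells 3.004 times higher (2.90 to 3.11). Parental cells thus had no enrichment over input there. The input had a median of 494.5 reads per window, against 13 in the lower windows as a set. Reads of many sequence copies may be counted together there, which was not tested, so the ratio cannot be assigned to 1 locus. The region on chromosome 12 from 114150001 to 114155400 fell from 9.93 to 5.21 times the input, with parental cells 1.91 times higher (1.80 to 2.01). On chromosome 11 from 115660801 to 115665300, signal fell from 12.9 to 6.15 times the input, a ratio of 2.09 (1.97 to 2.22). On chromosome 2 from 174122701 to 174126600 it fell from 23.9 to 10.7 times the input, a ratio of 2.24 (2.12 to 2.37). On chromosome 4 from 151933201 to 151937100 it fell from 9.91 to 4.14 times, a ratio of 2.39 (2.21 to 2.59). Of all 34 regions named by rule, 24 passed with an assumed coefficient of variation of 0.1 and 5 with 0.2.

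At the adjusted threshold, 6.05% of the lower regions were at least 3 windows long, against 0.777% of the higher regions, and together they covered 12.2 Mb and 0.620 Mb. Lower windows were far more numerous, which alone lets more neighbours merge, so these lengths do not show that losses were broader than gains. Bins of 1 Mb had a median of 35 lower and 10 higher listed windows. The 4 bins with the most lower windows were neighbours at the distal end of chromosome 8, from 122000001 to 126000000, with 2141 lower and 26 higher windows.

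Chromosome 8 stood apart from the other autosomes. It had 14134 listed windows, 110 per Mb, of which 6.84% were higher in Tet2kd cells (Wilson 95% interval 6.44% to 7.27%). Among the other autosomes that share ran from 13.3% on chromosome 7 to 25.5% on chromosome 13, and their density from 50.7 to 97.6 windows per Mb. The median log2 ratio was -0.999 on chromosome 8 and -0.86 over the other autosomes. Among the lower windows alone it was -1.03 on chromosome 8, against -1.001 on chromosome 14 and -0.92 on chromosome 10 as the extremes of the other autosomes. Chromosome X had 2916 listed windows, 12.9% of them higher, with a median log2 ratio of -1.12, and 5.67 input reads per window against 13.4 on the autosomes other than 8. Its medians were larger in both directions, at 2.37 in the higher and -1.18 in the lower windows. On the autosomes other than 8 they were 2.00 and -0.95. Windows with few reads need a larger ratio to be listed, so the -1.12 does not show a stronger loss on chromosome X. Chromosome Y had 99 listed windows, 6 of them higher.

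**Figure D2:**
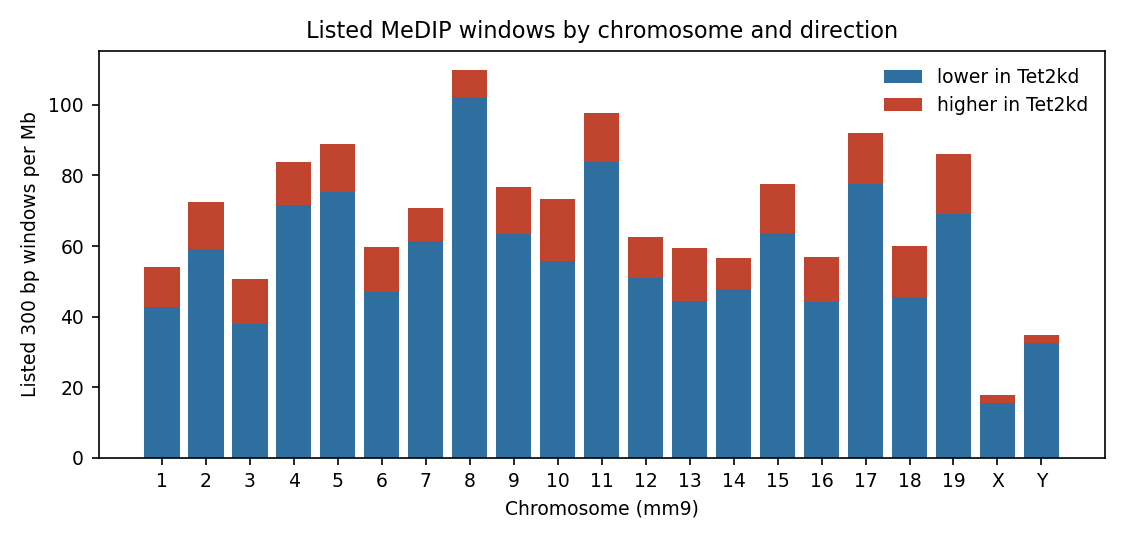
Listed windows per Mb on each chromosome, stacked as lower (blue) and higher (red) in Tet2kd cells. Bars are counts from 1 comparison and carry no replicate error. Chromosome 8 has 102 lower and 7.52 higher windows per Mb.

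One segment of chromosome 13 stood out by its excess of higher windows. From 54381001 to 55875000, 148 of 209 listed windows (70.8%) were higher in Tet2kd cells, against 168 of 1210 (13.9%) in the 5 Mb on each side. This was the segment with the largest excess of higher over lower windows of any chromosome, at 87. The next largest, on chromosome 6 from 92744401 to 93837600, had an excess of 29, with 49 of 69 windows (71.0%) higher. Segments were chosen for such an excess, so a majority of higher windows was built in. The best run of each chromosome had a majority, down to 59.3% on chromosome 1. The chromosome 13 segment thus differed by the size of its excess, not by its share. The pooled input was also higher in the chromosome 13 segment, at 19.6 ± 5.90 reads per window (SD over 209 windows) against 13.8 ± 5.27 in the flanks. The segment held 16 of the higher and 6 of the lower windows past the adjusted threshold.

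**Figure D3:**
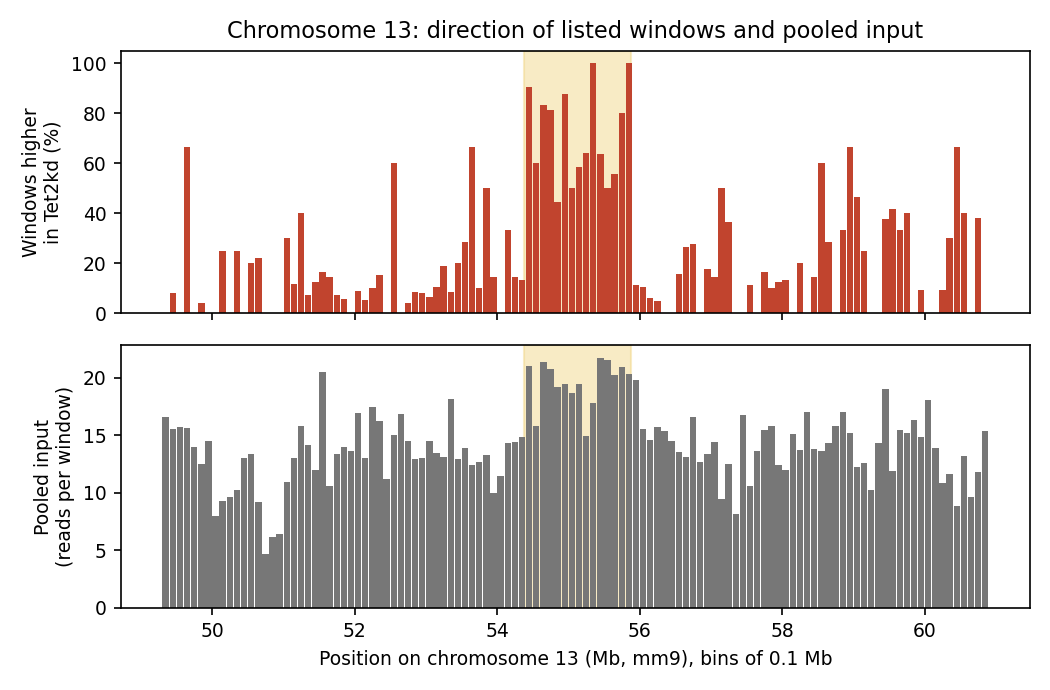
Share of listed windows that were higher in Tet2kd cells (top, percent) and mean pooled input reads per listed window (bottom), in bins of 0.1 Mb along chromosome 13 (mm9), with the segment from 54381001 to 55875000 shaded. Both are raised on average within the shaded segment, where 70.8% of the windows were higher and the input averaged 19.6 reads. The segment was chosen for its excess of higher windows.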

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

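The assumed variation, the Benjamini-Hochberg adjustment, the left-out chromosome and segment, and the by-chromosome medians past the adjusted threshold were chosen after seeing the data. Counts are of windows or regions past an adjusted p of 0.05, lower then higher in Tet2kd cells. With read totals alone, the windows went from 40167 and 2063 to 16968 and 5376, and the regions from 26779 and 1674 to 11983 and 4314. The listed lower windows with a p under 0.0001 went from 146356 to 83236. Windows outside the list could not be counted, so the higher counts under this scaling are minimums. With an assumed coefficient of variation of 0.05, 21310 and 1274 windows and 14933 and 1056 regions passed. With 0.1, 1453 and 323 windows and 1170 and 273 regions passed. With 0.2, 11 and 7 windows and 4 and 7 regions passed, and with 0.4, 0 and 0 of either. A larger assumed variation raises every p by construction. With the Benjamini-Hochberg adjustment all listed windows passed, 146356 and 31040. An adjusted p under 0.01, a mean of at least 20 reads, autosomes alone, merging by touch or within 1 kb, and leaving out chromosome 8 or the chromosome 13 segment kept the counts they were applied to within 1.5 times. Of the 34 named regions, 33 passed with read totals alone. The 17 higher ones passed by construction, since dropping the authors' scaling raises Tet2kd signal. Of the 17 lower ones, 16 passed.

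Median log2 ratios kept their sign, which says little because most listed windows were lower in Tet2kd cells. As ratios of totals they were -0.86 on chromosome 8, -0.66 on the other autosomes and -0.90 on chromosome X, and among windows past the adjusted threshold -1.12, -1.01 and -1.28. For the ratios of totals the cause was not tested, and a stricter threshold selects larger differences by construction. With at least 10 input reads per window, the parental and Tet2kd medians over input were 0.870 and 3.51 in the higher windows and 6.72 and 3.54 in the lower windows. Dividing by few input reads raises the ratio, which is by construction.

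No paired analysis was possible because the table has 1 column per line, without replicate numbers. For the same reason DESeq2, its size factors, the replicate block, leaving out replicates, and the input ratio between lines were not run. CpG density classes and gene lists were not run since the table gives no CpG count and no gene. A run without a count filter, and pseudocounts on RPKM, did not apply to this list of counts.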

Other observations

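Each test in this part was chosen after the result was seen, except that of window density on chromosome 8. Windows that gained signal in Tet2kd cells were most frequent on chromosome 10, with 17.5 per Mb against 8.78 on chromosome 14, the lowest among the autosomes other than 8. Chromosome 19 was close to chromosome 10, with 16.9 per Mb. Of the 12 bins of 1 Mb with the most gained windows, 6 lay on chromosome 10, though those at the top lay on chromosome 13. The latter held 73 and 83 gained windows from 54000001 to 56000000, around the segment described above. A further 63 lay from 114000001 to 115000000, outside it. Those on chromosome 10 included the neighbouring bins from 66000001 to 68000000, with 51 and 49 gained windows. On the same chromosome, the neighbouring bins from 79000001 to 81000000 were among those with the most lost windows, with 446 and 393, against 7 and 2 gained. A further region lower in Tet2kd cells lay near the end of chromosome X, from 166434901 to 166436400, with 849 parental and 122 Tet2kd reads, 8.16 times higher in parental cells (95% interval 6.74 to 9.95). Its 5 windows held 207 input reads, 41.4 per window against 5.67 per listed window on chromosome X, and parental and Tet2kd signals were 3.57 and 0.437 times the input. It was chosen after its values were seen, as 4 of its windows were among the 18 that passed with an assumed coefficient of variation of 0.2.

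Windows with over 100 pooled input reads numbered 92, of which 89 were lower in Tet2kd cells. Among all listed windows 82.5% were lower. Of the 92, 43 passed the adjusted threshold. Reads of many sequence copies may be counted together in such windows, which was not tested. The 7 on chromosome 2 from 98502301 to 98507400 had parental and Tet2kd signals of 0.938 and 0.798 times the input, a log2 ratio of -0.23, and 3 of them passed the adjusted threshold. The 20 on chromosome 17 from 39979801 to 39985800 had a log2 ratio of -1.59.

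The segment of chromosome 13 with 70.8% gained windows had a pooled input 1.42 times that of its flanks (95% bootstrap interval 1.36 to 1.49). A pile of reads in a few multi-copy windows is argued against, since 84.7% of the segment's windows lay above the flanks' median input. Input was 1.40 times the flanks (1.29 to 1.51) in the segment's lower windows as well. The input pools both lines, so its rise does not show that copies differed between them. A gain of methylation alone in Tet2kd cells is therefore not argued against. Extra copies in Tet2kd cells are a candidate explanation. If both lines made up the input alike, 1 copy added to 2 would give 1.25 and 2 copies 1.50. With an input all of Tet2kd, 1 copy would also give 1.50. The bootstrap interval leaves out variation of input between regions, so it does not tell 1 copy from 2. On the autosomes, median input of 1 Mb bins with at least 50 listed windows had an SD of 1.80 around 13. It was 18 and 19 in the 2 bins that hold the segment. Of 1258 bins, 4 were at 18 or above, these 2 included, and the highest elsewhere was 18. Extra copies would raise Tet2kd signal by 0.58 (1 copy) or 1 (2 copies) on the log2 scale. Median log2 ratios in the segment and its flanks were 1.89 and 1.81 in gained windows and -0.598 and -0.896 in lower windows. Over all listed windows they were 1.597 and -0.85, a pair that follows the mix of directions. The listing selects for large ratios, so these medians do not measure the rise. The input of each line alone was not analysed here, and methylation gains within an amplified segment stay open.

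The low share of gained windows on chromosome 8 held along its length: 14 of 14 segments of 10 Mb lay below the median share of the other autosomes' segments (21.6%), at 2.69% to 17.8%. Window density alone is argued against, since 14 of 14 also lay below the line fitted to the share and the number of windows elsewhere. Chromosome 8 was the 1 autosome with every segment below such a line. More copies of chromosome 8 in parental than in Tet2kd cells may account for it, and lower methylation along the chromosome may too, which was not tested. Input in gained windows was 12.3 reads on chromosome 8. It was 11.5 to 13.1 on the other autosomes, and 12.2 over them together. If both lines made up the input alike, 1 copy added to 2 would raise it 1.25 times, which was not seen. The share of each line in the pooled input is unknown, so a copy change and a methylation change cannot be told apart.

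The excess of lost windows could come from a weaker pull-down in the Tet2kd sample, from lower methylation, or from variation between cultures. Its size also depended on the scaling. Past the adjusted threshold, 4.89% of the windows were higher with the authors' scaling and at least 24.1% with read totals. Its direction rests on the column names, and exchanged names would turn lost windows into gained ones. In the gained windows Tet2kd signal had a median of 4.14 times the input, but the listing asks for Tet2kd reads far above parental ones, so this value does not decide on the pull-down. For the lost windows a weaker pull-down cannot be told apart from lower methylation. In 80.7% of them Tet2kd signal stayed at least 2 times the input, and enriched windows that did not differ, which would show whether the loss is general, are outside the list. Variation between cultures stays open as well, since 18 windows passed with an assumed coefficient of variation of 0.2 and no replicate columns were at hand to estimate it.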
